A study of Mus musculus with 12 samples.

How the data were processed

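The study profiled N6-methyladenosine (m6A), the most common internal modification of mRNA, in the livers of C57BL/6 mice by m6A RNA immunoprecipitation and sequencing (MeRIP-seq). Per the labels' protocols, fragmented poly(A) RNA was precipitated with an anti-m6A antibody, and stranded mRNA libraries were made from the precipitated (IP) RNA and from input mRNA. The labels give 12 libraries in 4 groups of 3 replicates: wild-type IP, wild-type input, Mettl3-deficient IP and Mettl3-deficient input.

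The values came from 1 table of the authors' own comparison between the genotypes, with 1 row per peak. Reads were aligned with HISAT2 2.1.0 to mm10, per the submitters' processing notes. The peak caller, its filters, the treatment of replicates and the settings of the comparison are not given in the sources used here. Per the file headers, the authors deposited for each peak a log2 fold change, the log10 of its false discovery rate (FDR), a p-value rounded to 2 decimals, genomic start and end, the gene, a feature class and the distance from the transcript start. The deposited log10 FDR is here called a score of evidence, because it has a floor: the lowest score is -434 and the next lowest -321. The width given by the authors runs from start to end on the genome and includes introns, up to 340372 bp, so it is not a length on the RNA. The deposited distances and widths are other measures that describe each peak and were used only to sort peaks into classes.

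The header does not say which genotype is the numerator of the fold change. METTL3 is the catalytic subunit of the m6A methyltransferase, and the design sets its deficiency against wild type, so a negative value likely stands for lower m6A enrichment in Mettl3-deficient liver. This reading rests on the design alone, and the text therefore speaks of negative and positive changes.

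The table held 17692 rows. In 189 of them the gene name was missing and the last cells stood in another order, and these were left out of the main counts. The other 17503 peaks lay in 10277 named genes. Of these names, 10015 matched a RefSeq symbol or synonym of assembly GRCm38.p6, which is the same build as mm10, and 97.9% of the leading peaks whose symbol matched overlapped the RefSeq span of their gene. The FDR values did not match a Benjamini-Hochberg adjustment over the listed rows alone. The number of tests that they implied was 29598 among peaks with a deposited p-value of 0.02 and 19745 among those with 0.5, so the share of peaks past the threshold is a share of the listed peaks and not of all peaks tested.

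A peak was called when its deposited FDR was 0.05 or below. No values per library were used here, so read depth is unknown, no error between mice could be computed, and no count model, replicate comparison or new test of a single peak was possible. The planned edgeR and limma fits, the IP enrichment within each genotype, the input RNA comparison and the motif search were not run. Shares of called peaks are given with 95% Wilson intervals, which cover counting error over peaks only. Peaks and genes are not independent replicates, so tests across them describe this table and not the variation between mice.

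For each gene, the leading peak was the one with the smallest FDR, ties being broken by the larger change. 20 gene lists for liver and m6A biology were fixed before the data were examined, as were the alternatives not described below as added and the rule for naming genes. That rule took the m6A writer genes and Hnf4a, the 10 most negative and 10 most positive leading peaks among called genes with an established symbol, and up to 4 called members of each list by FDR. Some genes that the rule takes are not reported here by name, though they stay in the counts and medians of their lists. Other genes in the text were chosen after their values were seen. The classes of exon position, the overlap with the transcript start, the comparison of peaks inside genes and the shares by chromosome were likewise added after the data were seen. A list's median log2 fold change was placed among 10000 random lists of as many genes, and a list was set apart when it fell outside the central 95%. The p-values of each list were also adjusted over the list alone, with 0.005 added to each for rounding. Enrichment of pathway terms of 15 to 500 called genes was tested with Fisher's exact test, two-sided, among called genes with an annotation in the table, with Benjamini-Hochberg adjustment. The steps were tested on simulated data: of 20 KEGG terms given a raised share of negative genes, 50.0% were recovered over 8335 genes, and none of 248 terms was called when no term was changed. Signs were redrawn there at a common rate for all genes. The simulation therefore does not cover false calls from terms that differ in their mix of features. Lists of 12 genes drawn mostly from negative genes were set apart in 32.0% of 200 draws, against 5.0% of random lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.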

Results

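The comparison between the genotypes asked how the m6A landscape of postnatal liver depends on Mettl3. It covered 17503 peaks in 10277 genes, from 3 wild-type and 3 Mettl3-deficient replicates, each with an IP and an input library. All fold changes and FDR values of single peaks are the authors' own, and counts, medians and shares were computed from them. The spread between mice is not known for any of them.

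Most listed peaks were called, and the larger changes were negative. Whether the deposited FDR takes in the variation between replicates is not known, so a called peak is not shown to exceed that variation. Of the 17503 peaks, 13345 (76.2%) passed the FDR threshold, 7107 with a negative and 6238 with a positive change. Negative changes had a median of -1.34 on the log2 scale (quartiles -1.84 and -0.93), a ratio of 0.395. Positive changes were smaller, with a median of 0.73 (quartiles 0.56 and 0.96), a ratio of 1.66. A change of at least 1 on the log2 scale was seen in 5070 negative peaks (71.3% of them) and in 1366 positive peaks (21.9%). Values near 0 were rare: 121 of all listed peaks lay within 0.25 of it. The median of all listed peaks was 0.34, and positive values below it turn negative when the changes are taken relative to that median. At the level of genes, 3782 had negative called peaks only, 3275 positive called peaks only and 1278 both, while 1942 had no called peak.

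**Figure D1:**
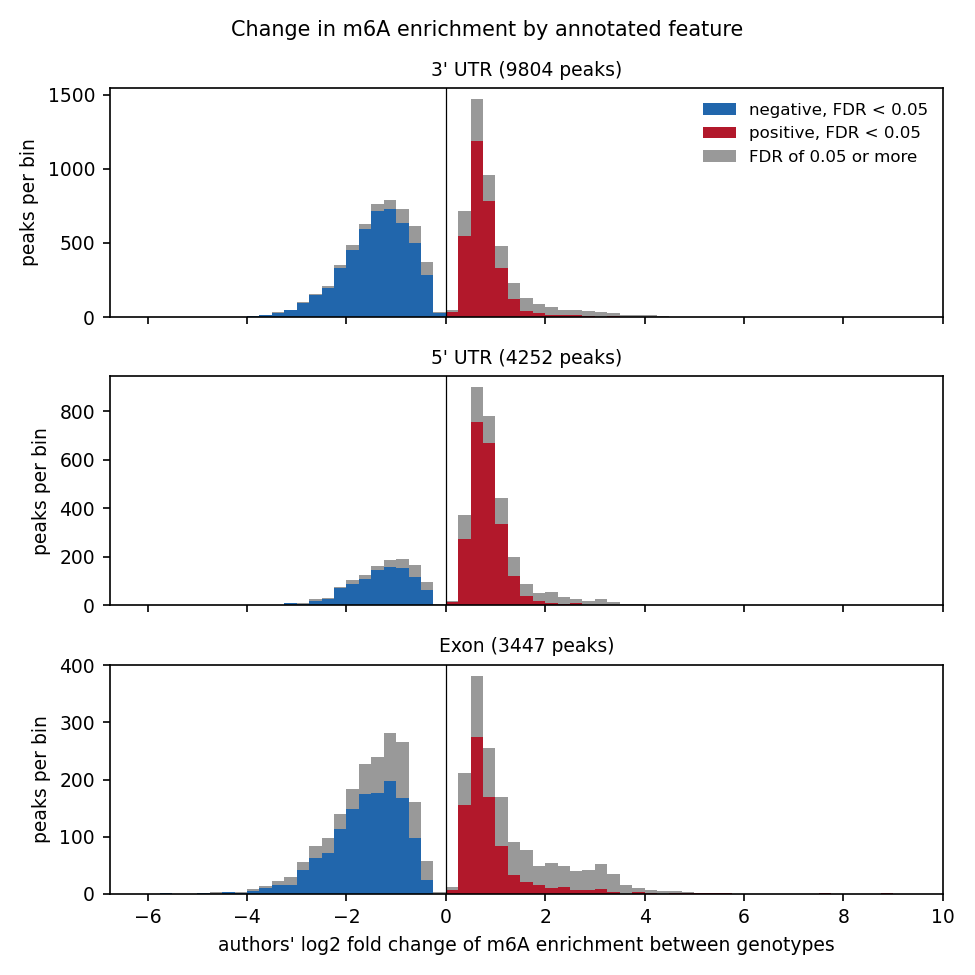
Number of peaks (y axis) by the authors' log2 fold change of m6A enrichment between genotypes (x axis, bins of 0.25), for peaks in the 3′ UTR, the 5′ UTR and other exons; colours give the sign of called peaks (FDR of 0.05 or below) and grey the peaks not called. Negative changes spread widely around a median of -1.34, whereas positive changes form a narrow band around 0.73 that holds most called peaks of the 5′ UTR.

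The transcripts of the m6A methyltransferase complex itself lay on the negative side. No peak of Mettl3 or Mettl14 was analysed here, so the targeted gene gives no check of the labels. In all 6 of the 8 writer genes with a listed peak, the leading peak was negative and called, and of their 16 peaks 14 were negative and called and none was positive and called. In the authors' deposited table the leading peaks stood at -2.16 in an exon of Rbm15, -1.57 in the 3′ UTR of Zc3h13, -1.51 in that of Rbm15b, -1.49 in that of Wtap, -1.49 in an exon of Virma and -1.41 in the 3′ UTR of Cbll1. All 6 genes encode accessory subunits of the complex. Their median of -1.50 lay at percentile 5.39 of random lists and was not set apart from other genes. Against random lists matched on feature and FDR it lay at percentile 33.3.

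Among the erasers and readers of m6A, 4 genes were negative, 3 positive and 2 not called. The YTHDF proteins are cytoplasmic readers of m6A. For their leading peaks the authors' deposited table gives -2.99 for Ythdf2 (3′ UTR, log10 FDR -434), -2.71 for Ythdf1 (exon, log10 FDR -434) and -1.85 for Ythdf3 (3′ UTR, log10 FDR -98.5). A further called peak in the 3′ UTR of Ythdf2 stood at 0.63 (log10 FDR -3.38) in the authors' deposited table. The same authors' deposited table gives positive called values for Hnrnpa2b1, with 1.18 in the 5′ UTR and a ratio of 2 at its leading peak, and for the demethylase gene Fto (1.13). Alkbh5, the other demethylase gene, had values of 0.32 and 1.05 in the authors' deposited table and was not called. The list's median of -0.97 lay at percentile 25.5 of random lists.

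Transcripts of hepatocyte transcription factors had the lowest median change of the 20 lists. Of the 16 genes with a listed peak, 15 had a negative leading peak and 1 a positive one, and all 16 passed the threshold. The list's median of -2.04 was lower than that of each of the 10000 random lists of its size, and its median over 3′ UTR peaks alone was -2.11 (percentile 0.01). Against random lists matched on feature and FDR, the median of -2.04 lay at percentile 0.63. In the authors' deposited table the leading changes were -2.81 in Foxa3, -2.66 in Hnf4a and -2.02 in Foxa2, each at the floor of the FDR scale. Cebpa (-1.92), Foxa1 (-2.57), Nr5a2 (-2.59) and the fatty acid receptor gene Ppara (-2.13) were also negative and called in the authors' deposited table. Foxa3 and Ppara each also held a called positive peak, at 0.57 and 0.89 there. The exception was Nr1i3, which encodes the xenobiotic receptor CAR, at 0.98 in the authors' deposited table. The wider GO term of DNA-binding transcription factor activity was also more often negative than its background, as given below. Whether the hepatocyte list differs from transcription factor genes in general was not tested.

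Hnf4a, which encodes a nuclear receptor central to hepatocyte identity, had 3 called peaks of differing sign. Its RefSeq span on mm10 runs from 163506811 to 163572907 on chromosome 2. The authors' deposited table places the negative peak at 163570122 to 163570601 (480 bp, annotated 3′ UTR), with a log2 fold change of -2.66, a ratio of 0.158. A peak near the end of the gene, at 163572700 to 163572910 and also annotated 3′ UTR, stood at 0.67 (log10 FDR -56.3) in the authors' deposited table. The third peak, at 163546907 to 163550234 in the 5′ UTR, stood at 0.61 (log10 FDR -23.2) there.

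**Figure D2:**
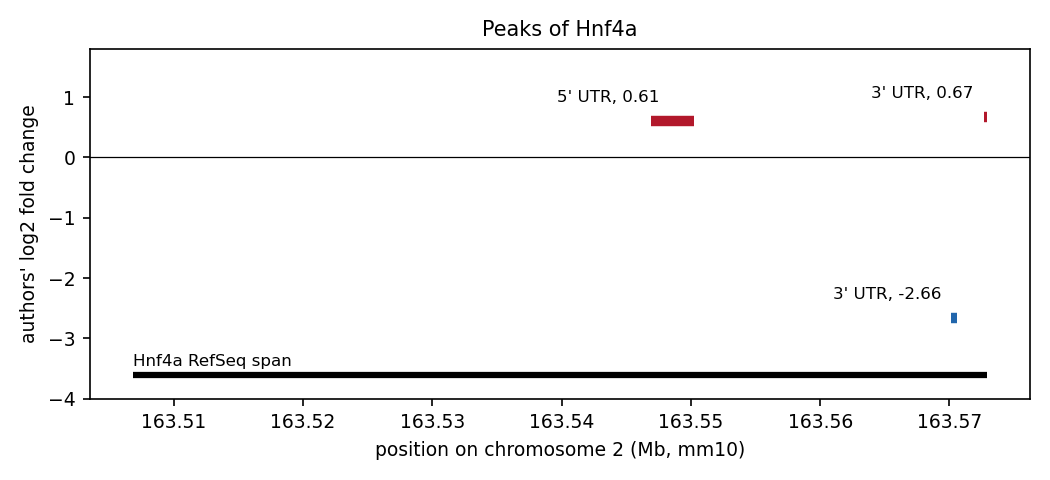
Position on chromosome 2 (x axis, Mb, mm10) and the authors' log2 fold change (y axis) of the 3 peaks of Hnf4a, with the RefSeq span of the gene as a black bar. The peak starting at 163570122 stands at -2.66, between peaks at 0.61 and 0.67.

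By leading peak, the listed genes of 4 hepatocyte functions were more often negative than positive, while larger pathway sets of related function went both ways. Of all genes with a called leading peak, 58.6% were negative, so a negative majority alone does not set these lists apart. In drug metabolism all 6 genes with a listed peak were negative and called, and in bile acid and sterol handling 8 of 12 were negative and 4 positive. Fatty acid and glucose genes were negative in 8, positive in 3 and not called in 1 of 12, and urea cycle and amino acid genes were negative in 5 and positive in 2 of 7. Over all called peaks, drug metabolism had 8 negative and 1 positive and fatty acid and glucose genes 13 and 7, but bile acid and sterol genes were even at 12 and 12, and urea cycle and amino acid genes at 5 and 5. The 5 negative urea cycle and amino acid genes include Tdo2, whose only listed peak lies outside its RefSeq span. Among the KEGG terms, which were examined after the data were seen, 9 of 28 called genes of cytochrome P450 drug metabolism were negative (adjusted p = 0.202, Fisher's exact test across genes, two-sided), as were 10 of 31 of glycolysis and gluconeogenesis (adjusted p = 0.182) and 13 of 28 of fatty acid degradation (adjusted p = 0.791), while bile secretion had 21 of 35 (adjusted p = 0.703). None of these 4 terms was called, whereas the GO term glucuronosyltransferase activity was, with 18 of 19 negative (adjusted p = 0.0145, the same test). The authors' deposited table gives -1.94 for Cyp1a2 and -1.29 for Cyp2e1 (cytochrome P450 enzymes), -2.17 for Cyp8b1 (a hydroxylase of bile acid synthesis), -2.18 for Hsd3b7 (also of bile acid synthesis) and -1.82 for Slc10a1 (the main bile acid uptake carrier). It also gives, for fatty acid oxidation and fatty acid synthesis, -2.19 for Cpt2, -1.99 for Cpt1a and -2.12 for Acaca, and -2.11 for G6pc, which encodes the glucose-6-phosphatase of glucose release (authors' deposited table). In drug metabolism the authors' deposited table also gives -1.35 for Ugt2b5, a member of a family of similar genes among which reads can be shared, and -1.18 for Cyp3a13. For nitrogen metabolism the authors' deposited table gives -1.26 for the urea cycle gene Arg1 and -0.78 for the glutamine synthetase gene Glul. These values are of leading peaks, and Hsd3b7, Cpt1a, Arg1 and Glul also held called positive peaks in the authors' deposited table. Medians of these lists were -1.32, -1.22, -1.07 and -0.96 in the order named, and none was set apart from random lists (percentiles 9.98, 7.87, 15.2 and 28.1). Against random lists matched on feature and FDR, an alternative added after the data were seen, the percentiles were 76.4, 63.0, 93.5 and 78.9. Compared with such genes, these lists were therefore not on the more negative side. With the mean over the peaks of each gene, the medians were -1.27, -0.25, -0.445 and -0.115.

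The list of abundant secreted liver proteins, which also holds the intracellular enzyme gene Tat, was split. Of 15 genes, 6 had a negative and 9 a positive leading peak. In the authors' deposited table Apob (-2.05), Fga (-1.37), Hp (-1.27) and Tat (-1.22) were negative, while Alb (0.81) and Ttr (0.93) were positive, all at the floor of the FDR scale. Apoa1 held both signs, with 0.55 in the 5′ UTR and -1.11 in the 3′ UTR in the authors' deposited table. Apob also held a called positive peak, at 0.86 in the 5′ UTR there. The list's median of 0.55 was at percentile 82.1 of random lists, but at percentile 99.98 of lists matched on feature and FDR, while over the 3′ UTR peaks of 14 genes alone the median turned to -0.535 (percentile 54.7). Both alternatives were added after the data were seen.

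**Figure D3:**
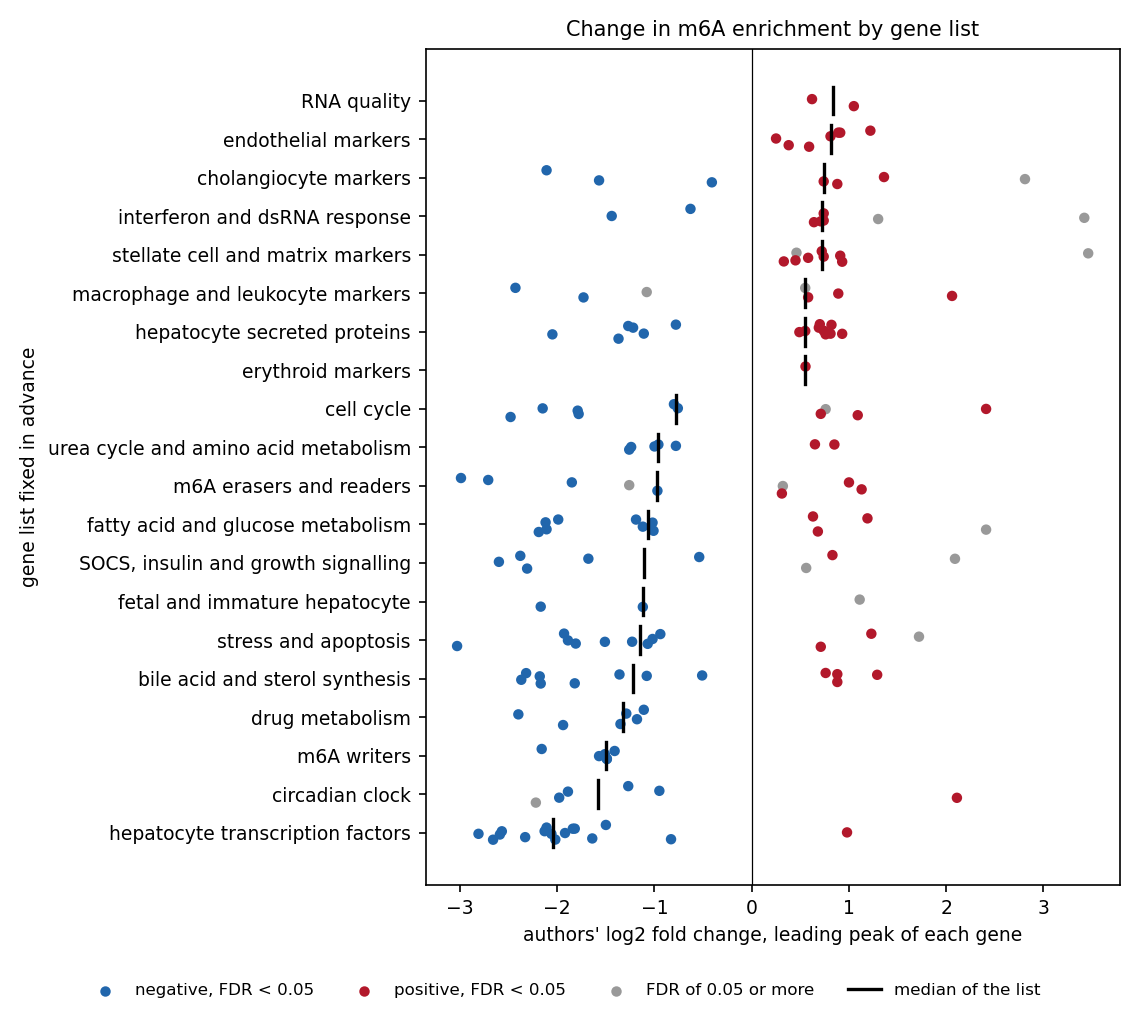
The authors' log2 fold change of each gene's leading peak (x axis) for the 20 gene lists fixed in advance (y axis, ordered by median); colours give the sign of called genes, grey points were not called and black bars are list medians. Hepatocyte transcription factors have the lowest median (-2.04), and no called endothelial or stellate marker gene is negative on the values as deposited.

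Markers of endothelial and stellate cells, by contrast, had no negative called peak. All 7 endothelial genes with a listed peak were positive and called, as were 7 of 9 stellate and matrix genes, with 2 not called. The authors' deposited table gives 0.81 for Pecam1, 0.89 for Stab1, 0.38 for Clec4g and 0.25 for Cdh5, which are endothelial surface proteins. For matrix and stellate genes the authors' deposited table gives 0.72 for Dcn, 0.93 for Lum, 0.58 for Col1a1 and 0.33 for Pdgfrb. Medians were 0.81 (percentile 93.9) and 0.72 (percentile 92.1), neither set apart from random lists. The changes were small: of the leading peaks of these 14 called genes, only that of Lyve1 reached an absolute log2 fold change of 1, at 1.22 in the authors' deposited table. Other called peaks above 1 in the authors' deposited table were those of Tgfb1 (1.04) and Flt1 (1.12), both in the 3′ UTR. Relative to the median of all listed peaks, 0.34, Cdh5 and Pdgfrb turn negative. Macrophage and leukocyte markers went both ways: the authors' deposited table gives -2.43 for Csf1r, the receptor of a macrophage growth factor, and -1.73 for Cd14, but 0.58 for Lyz2 and 2.06 for Cd79a. Both listed peaks of Csf1r lie past the RefSeq end of the gene at 61131139 on chromosome 18, the leading one at 61131816 to 61132414, so they are tied to it by the authors' annotation alone. In that list 2 genes were negative, 3 positive and 2 not called. Cholangiocyte markers were negative in 3, positive in 3 and not called in 1 of 7, with Sox9 at -1.57, Spp1 at -0.41 and Krt8 at 0.74 in the authors' deposited table. Of the erythroid markers only Hbb-bs was listed, at 0.55 in the authors' deposited table, and it shares most of its sequence with a neighbouring globin gene. In the RNA quality list, the authors' deposited table gives 1.05 for Rplp0 and 0.62 for the leading peak of mt-Nd4.

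Stress and growth genes were more often negative than positive, but so were all genes with a called leading peak, of which 58.6% were negative. Of 12 stress and apoptosis genes, 9 were negative, 2 positive and 1 not called. The authors' deposited table gives -3.03 for Gdf15, a stress-induced hormone gene, -1.51 for the chaperone gene Hspa5 and -1.81 for the pro-apoptotic gene Bbc3, but 1.23 for the leading peak of the pro-apoptotic gene Bax. That peak, at 45465984 to 45475734 on chromosome 7, lies mostly past the RefSeq end of Bax at 45466903, and the 2 peaks within the gene stood at 0.61 and 0.64 in the authors' deposited table. Cell cycle genes were negative in 6, positive in 3 and not called in 1 of 10, with Myc at -2.48, Mdm2 at -2.15, E2f8 at -1.79 and Trp53 at 0.71 in the authors' deposited table. Of 8 genes of SOCS, insulin and growth signalling, 5 were negative, 1 positive and 2 not called, and the authors' deposited table gives -2.60 for Irs2, -2.38 for Insr, -2.31 for Igfals and -0.54 for Ghr. Ghr also held a called positive peak, at 0.71 there. Circadian clock genes were negative in 4, positive in 1 and not called in 1 of 6, with Nr1d2 at -1.98, Per2 at -1.89, Tef at -1.27 and Cry2 at -0.95 in the authors' deposited table. Interferon and double-stranded RNA response genes were negative in 2, positive in 4 and not called in 2 of 8, including Ddx58 at -1.44, Irf7 at 0.71 and Zbp1 at 0.74 in the authors' deposited table. Of 3 genes of the immature hepatocyte list, Peg3 (-2.17) and Zbtb20 (-1.12) were negative and called in the authors' deposited table and Afp, at 1.11, was not called. The leading peak of Zbtb20, at 43640953 to 43641223 on chromosome 16, lies past the RefSeq end of the gene at 43634392. So does a called positive peak annotated to it, at 0.72 in the authors' deposited table. The medians were -1.15, -0.78, -1.11, -1.58, 0.725 and -1.12 in the order named (percentiles 11.1, 33.1, 17.3, 3.81, 91.9 and 28.8), and none of these lists was set apart. Over all called peaks, stress genes had 11 negative and 8 positive, cell cycle genes 7 and 4, and growth signalling genes 10 and 2. Adjusted over the list alone, the number of genes past the threshold was the same in 19 of the 20 lists, the exception being the leukocyte list with 6 in place of 5.

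The sign of the change differed between the annotated features. Each peak carries a single feature label, even where it is wide: the peaks of Cyp8b1 and Foxa2 labelled 5′ UTR cover the whole RefSeq span of the gene. Shares by feature therefore follow the authors' labels and not exact positions. The 3′ UTR share also stayed above the 5′ UTR share with peaks of up to 1000 bp, as given below. In the 3′ UTR 60.4% of 7943 called peaks were negative (95% Wilson interval 59.3 to 61.5), against 30.1% of 3249 in the 5′ UTR (28.5 to 31.7) and 61.8% of 2153 in other exons (59.7 to 63.8). Among called peaks with an absolute log2 fold change of at least 1, the negative share in the 5′ UTR was 53.5% and that in the 3′ UTR 85.1%. Among exon peaks, those in the last exon were negative in 84.1% of 465 (80.5 to 87.1) and those in internal exons in 57.4% of 1262 (54.6 to 60.1). First exons, at 60.1% of 223 (53.5 to 66.3), were not lower than internal exons, and peaks of single-exon transcripts were negative in 39.9% of 203 (33.4 to 46.8). Peaks of the 5′ UTR that covered the transcript start were negative in 25.8% of 2680 (24.2 to 27.5), and those away from it in 50.3% of 569 (46.2 to 54.4). With the leading peak of each gene alone, the odds of a negative change in the 3′ UTR were 3.76 times those in the 5′ UTR (Fisher's exact test across genes, two-sided p = 1.77e-122).

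The same contrast held inside genes. Called peaks were present in both UTRs of 1475 genes. The leading peak was positive in the 5′ UTR and negative in the 3′ UTR in 521 of them, and the opposite in 86 (exact binomial test across genes, two-sided p = 7.52e-77). Both were positive in 576 genes and both negative in 292. The median difference, 3′ UTR minus 5′ UTR, was -0.45 on the log2 scale.

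The share of negative peaks was lower on the X chromosome than on any autosome. Of 243 called peaks on X, 39.1% were negative (95% Wilson interval 33.2 to 45.4), against 53.5% of 13100 on the autosomes (52.7 to 54.4). Shares of single autosomes ran from 48.6% on chromosome 17 to 60.3% on chromosome 12. X was singled out after its value was seen.

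**Figure D4:**
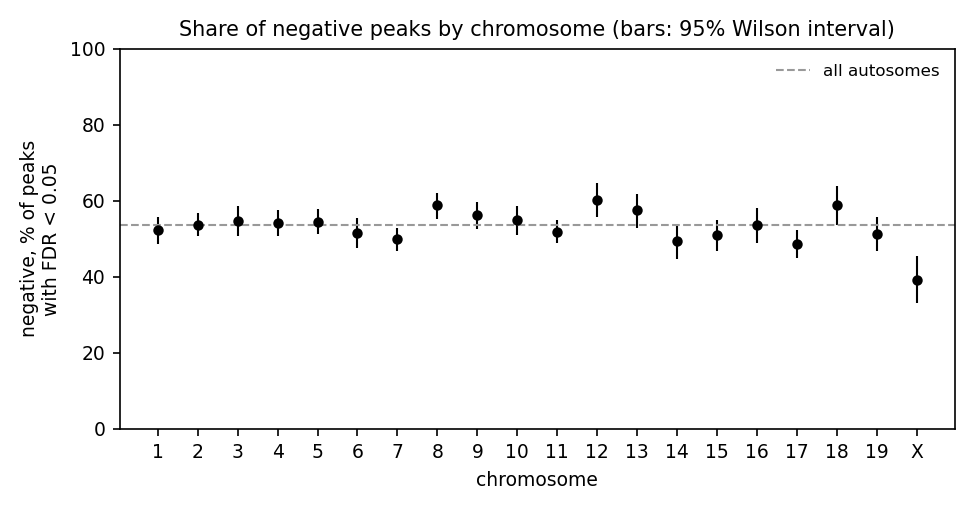
Negative peaks as a percentage of called peaks (y axis) on each chromosome (x axis), with 95% Wilson intervals as bars and the share of all autosomes as a dashed line. X stands at 39.1%, below the autosomes, which run from 48.6% to 60.3%.

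Among called leading peaks of genes with an established symbol, the most extreme had, with few exceptions, modest support. Called peaks of all kinds ran from -5.70 to 8.99. Within that set, the most negative in the authors' deposited table were those of Mob3b (-4.55, log10 FDR -114), Zfp420 (-4.50), Kiss1r (-4.47), Rasal1 (-4.40), Acot6 (-4.37) and the thiamine carrier gene Slc19a2 (-4.01, log10 FDR -206), followed by Fam184b (-3.98), Hnrnpll (-3.95), Il17re (-3.93) and Zfp560 (-3.87). Mob3b also held a called positive peak in its 3′ UTR, at 0.66 (log10 FDR -4.36) in the authors' deposited table. On the positive side of the same set the authors' deposited table lists Rpl30 (7.70, log10 FDR -434), then Gpc2 (5.39), Sarnp (5.39), Dnajc27 (5.30), Dynlt1a (5.25), Cit (5.17), Rbms3 (5.09), Syt15 (4.91), Pcdhga9 (4.91) and Blk (4.67), with log10 FDR values between -3.16 and -1.33 after Rpl30. At FDR of 0.01 or below, Gpc2, Sarnp, Cit, Rbms3, Syt15, Pcdhga9 and Blk were no longer called. Rpl30, like other ribosomal protein genes, has processed pseudogenes that can share its reads. Pcdhga9 lies in a gene cluster whose transcripts share exons, so its reads cannot be assigned with certainty.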

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

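The 189 rows without a gene name lay outside the comparisons, and their cells were put back in order only after the values were seen. Of them, 121 passed the FDR threshold, 70 with a negative and 51 with a positive change. They also hold a number of between 1.20 and 68.5 (median 4.27) whose meaning no header gives and which the other rows lack.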

How the results depend on the processing

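No paired analysis was possible because the table holds the authors' comparison and no values per library, and for the same reason no replicate could be left out and the alternatives on normalization, tool, scaling of IP libraries, low values, pseudocount, IP without input and estimated correlation were not run. The motif alternatives, which need a genome, were not run either. The alternatives on rows with displaced cells, overlapping rows, centring, 3′ UTR peaks alone and matched lists were added after seeing the data. Counts of 7107 negative and 6238 positive peaks stayed within 1.5 times under FDR of 0.01 or below, removal of overlapping rows, addition of displaced rows and recentring on the median of 0.34. Negative peaks fell to 4375 with peaks of up to 1000 bp. Positive peaks fell to 1366 with an absolute log2 fold change of at least 1, 3448 with a single leading peak per gene, 3875 with peaks of up to 1000 bp and 3325 in the better supported part of the peaks by FDR. The negative share of 3′ UTR peaks was 63.5% at the stricter FDR, 85.1% with the fold limit, 65.7% with leading peaks, 56.2% with the width limit, 70.3% in the better supported part and 62.1% after recentring. That of 5′ UTR peaks was 53.5% with the fold limit, 33.8% with leading peaks, 23.4% with the width limit, 36.3% in the better supported part and 31.7% after recentring. That of other exons was 64.0% at the stricter FDR, 83.0% with the fold limit, 67.4% with the width limit and 67.8% in the better supported part. The cause of these shifts was not tested. The 3′ UTR share stayed above the 5′ UTR share in each alternative run. Among gene lists, the transcription factors stayed set apart under each alternative and no list changed sign while set apart. Lists that were not set apart changed sign with 3′ UTR peaks alone (secreted proteins -0.535, cholangiocyte markers -0.345) or with the mean over peaks (leukocyte markers -0.07, immature hepatocyte genes 0.125). Also set apart were endothelial markers with the mean over peaks (1.09) and with 3′ UTR peaks alone (0.85), and the circadian list with the mean over peaks (-1.42). Both endothelial values take in a 3′ UTR peak of Clec4g that was not called. The mean over peaks also takes in such peaks of Stab1, Flt1 and Tek. Against lists matched on feature and FDR, secreted proteins (0.55) and the RNA quality list (0.835) were set apart, the latter with only 2 listed genes. Of the 95 genes named by the rule, 7 were lost at FDR of 0.01 and 21 with the fold limit. What depth limits cannot be given, since read depth is unknown.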

Other observations

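Oxidative phosphorylation, ribosome and proteasome genes were mostly positive. The KEGG and GO terms in these opening paragraphs were tested after the data were seen, among called genes by leading peak (Fisher's exact test, two-sided). Of 248 KEGG terms, 29 passed an adjusted p of 0.05, 18 with fewer and 11 with more negative genes than the background of 52.0% over 3144 genes. In oxidative phosphorylation 4 of 73 genes were negative (adjusted p = 1.51e-15), in the ribosome 16 of 86 (adjusted p = 1.51e-08), in the proteasome 3 of 27 (adjusted p = 0.000495) and in the citrate cycle 2 of 19 (adjusted p = 0.00534). Their median changes were 0.64, 0.63, 0.64 and 0.63 in the order named, inside the narrow band of positive changes described below. A common scaling shift stays open for that band, so a low negative share does not establish a gain of m6A. More often negative were the terms herpes simplex virus 1 infection, with 134 of 180 (adjusted p = 1.70e-08), and pluripotency signaling, with 54 of 71 (adjusted p = 0.000834). So were ErbB signaling, with 39 of 51 (adjusted p = 0.00636), and Notch signaling, with 21 of 26 (adjusted p = 0.0284). With 3′ UTR peaks alone, adjusted p was 4.83e-10 for oxidative phosphorylation (4 of 47 negative), 7.66e-06 for the ribosome (13 of 58), 0.0364 for the proteasome (3 of 17) and 0.0214 for ErbB signaling (33 of 40). The herpes term (105 of 138, adjusted p = 9.15e-05) and the pluripotency term (47 of 62, adjusted p = 0.0430) also stayed called with these 3′ UTR peaks. Notch signaling was no longer called with them (17 of 21, adjusted p = 0.221), and the citrate cycle had too few genes to be tested. RNA transport, with 45 negative genes of 90 (adjusted p = 0.914), and Ras signaling, with 50 of 97 (adjusted p = 1), were not called.

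Of 1372 GO terms, 117 passed an adjusted p of 0.05, 99 with fewer and 18 with more negative genes than their background of 58.9% over 7854 genes. DNA-binding transcription factor activity had 262 negative genes of 328 (adjusted p = 1.04e-13) and glucuronosyltransferase activity 18 of 19 (adjusted p = 0.0145), while collagen-containing extracellular matrix had 22 of 108 (adjusted p = 1.04e-13). With 3′ UTR peaks alone, adjusted p was 1.22e-06 for the transcription factor term (209 of 265) and 2.97e-12 for the matrix term (21 of 91), and glucuronosyltransferase activity had too few genes to be tested. Genes of that term share exons and sequence, so their peaks are not independent. Among 105 genes with the orthology entry of KRAB zinc finger proteins, a group chosen after the data were seen and counted without a test, 77 were negative, 2 positive and 26 not called, with a median of -1.58. These proteins are repressors encoded by a large family of similar genes, among which reads can be shared. How many of these genes also belong to the herpes term above was not counted, so this count and that term are not shown to be separate results.

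Of the tests below, those on the location of marker peaks, on all 20 lists at once, on the other cell types and on a common scaling shift were chosen after their result was seen. Endothelial and stellate markers had 0 negative genes among 14 called, and the 2 lists were singled out of 20 for this, while neither list's median was set apart from matched random lists (percentiles 92.9 and 79.3). Of their 12 called 3′ UTR peaks 0 were negative (upper 95% Wilson bound 24.2%, against 60.4% of all called 3′ UTR peaks), but the choice of the lists fixed this, so it decides nothing about location. Lists matched on feature and strength of evidence had as few negative genes in 0.02% of draws. To allow for the choice, all 20 lists were also drawn. Lists without a negative gene then held 17 or more called genes, as observed, in 0 of 10000 draws. Those 17 also take in 2 genes of the RNA quality list and 1 erythroid gene. Both kinds of draw treat genes as independent, and the measure over all 20 lists was built from the pattern itself. Relative to the median of all peaks Cdh5 and Pdgfrb turn negative, so neither of the 2 lists would then lack a negative gene. Draws on the values as deposited thus rarely gave such lists. They do not exclude location and strength of evidence as the whole cause. A candidate explanation that stays open is that these cells kept Mettl3 activity, which the labels do not state. The leukocyte and cholangiocyte markers do not decide it, with 45.5% of 11 called genes negative (21.3 to 72.0), or 40.0% of 10 (16.8 to 68.7) without Csf1r, whose peaks lie past its RefSeq span.

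Positive changes formed a narrow band: the 465 positive peaks with a log10 FDR of -50 or below had an interquartile range of 0.24 around a median of 0.68, against 0.868 around -1.75 for 1990 negative peaks of the same support. Their medians were 0.65 in the 3′ UTR, 0.70 in the 5′ UTR and 0.66 in other exons. Positive peaks of genes without and with a negative called peak had medians of 0.72 and 0.74, a difference of -0.02. The positive changes were thus no larger in genes without a negative called peak. Both medians cover only peaks already chosen as positive, so they cannot decide whether a separate set of transcripts carries the rise. A common scaling shift of peaks without a true change stays open, since the narrow range is the pattern itself and could have excluded it but does not support it. A true change of methylation stays open too, as does its direction between the genotypes.

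Peaks on the X chromosome were less often negative. The share was 39.1% of 243 called peaks (95% Wilson interval 33.2 to 45.4) against 53.5% on the autosomes, whose lowest share was 48.6% (chromosome 17). Autosomal peaks of the same feature, width and strength of evidence gave an expected share of 47.4%, above that interval. The interval treats peaks as independent and makes no allowance for the choice of X after its value was seen. This mix may therefore account for part of the gap, and it is not excluded as the whole cause. With a single leading peak per gene the share was 40.4% (33.5 to 47.8), below the lowest autosome at 53.8%, which argues against a few genes with many peaks. Differences in expression level or in motif content of X-linked transcripts stay open and were not tested.

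A single peak in the 3′ UTR of Rpl30, at 34440505 to 34440774 on chromosome 15, stood at 7.70 in the authors' deposited table with the lowest FDR listed, while the peaks annotated to its 5′ UTR, at -0.52 and -0.43, were not called and lie outside its RefSeq span of 34440505 to 34443276.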
